A study of Mus musculus with 29 samples.

How the data were processed

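Each of the 29 libraries was made from the heart of 1 mouse. Per the labels' protocols, about 200 mg of heart was lysed, 50 to 100 ng of total RNA went into a stranded library kit without selection of polyadenylated RNA, and 50 bp paired-end reads were sequenced. The authors deposited 1 table of raw read counts per RefSeq gene, and the values are whole numbers with totals that differ between libraries. The submitters' processing notes name STAR 2.4.2a, DESeq2 1.24.0 and the mm10 genome build, without the role of each. The counting tool, its strand setting and the time of day of tissue collection are not given in the sources used here. Reads of near-identical genes can be split or lost by counting, so the values of ribosomal protein genes, Mt1 and Mt2, Hspa1b, Scd3, Csf2rb2 and the Serpina3 family are uncertain, as are those of overlapping and antisense genes. Of 20236 accessions matched to the RefSeq table of GRCm38.p6, 11362 had its start after adding 1 and 722 as given, so starts were raised by 1. A column was used only where its name matched a sample's labels, and 1 per-sample column that matched none was not used.

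Groups were taken from the labels' vector and treatment, and separate animal numbers in the labels make each library an independent animal. The comparisons, the tests, the gene lists, the rule for named genes and a first set of alternatives were fixed before the data were examined. Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 12928 of 20411, libraries were scaled by TMM factors, and 1 quasi-likelihood model with a mean for each of 4 groups was fitted to all libraries without covariates. Genes passed at a Benjamini-Hochberg adjusted p under 0.05. The standard error of a log2 fold change is its size divided by the square root of the F statistic. CPM values are scaled by the same factors. With 3207497 to 16853646 counts per library, a gene at 1 CPM has few counts in the smallest libraries.

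The 42 gene lists, 25 of pathways and 17 of cell type markers, held 848 entries, of which 826 were in the table (811 by symbol, 13 by an older symbol and 2 by accession) and 736 were tested. One list, of transcripts of the mitochondrial genome, had no gene in the table, so 41 lists were tested. They were compared with all other genes by camera on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the lists within a comparison, and again with an estimated correlation and with fry. Members are also counted with p-values adjusted over the list alone. No call passed with the estimated correlation except the acute phase and cell cycle lists for the tumour effect in REV-ERBα mice.

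Named genes were Nr1d1, the 8 largest rises and 8 largest falls of each of the first 4 comparisons among genes that passed, had a mean of at least 5 CPM and had a proper symbol (where none passed, the 5 smallest p-values), and up to 4 members of each list with the smallest p in the first 2 comparisons. The members Trim63, Fbxo32, Fkbp5 and Timp1 were named after their values were seen. Some single genes are not reported here.

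The whole procedure was tested on simulated data with 200 changed genes and, for each gene, the same spread in all groups. It recovered 70% and 83% of 100 genes changed 1.5-fold and 100 changed 2-fold for the tumour effect in GFP mice, with 11 false calls, 80% and 94% for the REV-ERBα effect in tumour-bearing mice with 14, 51% and 69% for that effect without a tumour with 1, and 66% and 92% for the tumour effect in REV-ERBα mice with 4. No pair of libraries held the same counts within sampling noise (lowest chi-square per degree of freedom 2.73 over 406 pairs).

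Alternatives fixed at the start were other scaling (RLE, upper quartile), DESeq2 1.42.0, other filters, a replicate block, a fit of only the compared groups, robust fitting, limma voom with sample weights, 1 surrogate variable (sva 3.50.0), an adjusted p under 0.1, removal of mitochondrial, ribosomal RNA and haemoglobin genes, and leaving out each library in turn. Added after the data were seen were leaving out the 5 libraries above 10000000 counts or the 9 with a mean atrial marker level above 5 log2 CPM, depth class, atrial or hepatocyte score as a covariate, and thinning to the smallest total. The C26 score was also chosen after the data were seen. Score differences were tested by two-sided permutation of labels, exact for a difference of groups where 1 had fewer than 10 animals, and with 100000 resamples otherwise and for the interaction. For each comparison, 100 splits of the animals were fitted, the real one among them.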

Results

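Hearts of BALB/c mice were profiled by total RNA sequencing after a viral vector and a tumour were combined in 4 groups. The vector was an adeno-associated virus with the Tbg promoter, which is active in hepatocytes, and it carried either green fluorescent protein (GFP) or REV-ERBα, a nuclear receptor that represses transcription in the circadian clock. The vector was given 10 days before C26 colon tumour cells. These are a model of cancer cachexia, the wasting of muscle and fat during tumour growth, and mice without a tumour received saline (PBS). PBS_GFP held 4 hearts, PBS_REVERBa 5, C26_GFP 10 and C26_REVERBa 10, each from an animal with its own number in the labels. The 29 libraries held between 3207497 and 16853646 counts. The lowest and highest totals were 3467940 and 14740569 in PBS_GFP, 3207497 and 5355029 in PBS_REVERBa, 5684452 and 16853646 in C26_GFP, and 3376113 and 7619837 in C26_REVERBa. Of 20411 genes in the table, 12928 had enough counts to be tested. Fold changes are log2 values from edgeR's quasi-likelihood test, given with their standard error, and adjusted p-values are Benjamini-Hochberg values over those genes unless another test is named.

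Nr1d1, the mouse gene of REV-ERBα (NM_145434, chromosome 11, 98767932 to 98775377, minus strand, mm10), had 195 ± 39.5 CPM (counts scaled to library size; SD, n = 4) in PBS_GFP hearts and 199 ± 33.8 CPM (SD, n = 5) in PBS_REVERBa hearts. It had 137 ± 41.4 CPM (SD, n = 10) in C26_GFP hearts and 166 ± 42.9 CPM (SD, n = 10) in C26_REVERBa hearts. The REV-ERBα vector changed heart Nr1d1 by 0.03 ± 0.24 without a tumour (edgeR adjusted p = 1) and by 0.28 ± 0.16 with one (edgeR adjusted p = 0.288). The vector's Tbg promoter is active in hepatocytes, so heart counts of mouse Nr1d1 do not check which vector an animal received. The species of the vector's REV-ERBα sequence is also not given in the sources used here.

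The first comparison asked what a C26 tumour does to the heart of mice given the GFP vector. The largest rise among the named genes was that of Serpina3n, a secreted protease inhibitor of the acute phase response (NM_009252, chromosome 12, 104406708 to 104414329), from 12.5 ± 6.89 CPM (SD, n = 4) in PBS_GFP to 433 ± 209 CPM (SD, n = 10) in C26_GFP hearts. Its lowest C26_GFP heart, at 216 CPM, lay above its highest PBS_GFP heart, at 22.8 CPM. The log2 change was 5.02 ± 0.53 (edgeR adjusted p = 1.68e-07). Lcn2, an iron-binding protein of inflammation (NM_008491, chromosome 2, 32384637 to 32387739), rose by 4.48 ± 0.77 (edgeR adjusted p = 9.61e-05), and the metallothionein gene Mt2 by 3.86 ± 0.51 (edgeR adjusted p = 4.42e-06). The cell cycle inhibitor Cdkn1a rose by 2.93 ± 0.63 (edgeR adjusted p = 0.00089), with a wide spread of 30.9 to 446 CPM among C26_GFP hearts. Apln, the peptide ligand of the apelin receptor (NM_013912, chromosome X, 48025146 to 48034852), had the largest fall, from 39.5 ± 8.10 CPM (SD, n = 4) to 4.11 ± 3.43 CPM (SD, n = 10). Its log2 change was -3.23 ± 0.42 (edgeR adjusted p = 3.42e-06). Apod, Clca3a1, Mmp3 and Scd3 also rose, by 3.49, 3.26, 3.05 and 2.93. Rtn4r, the transcription factor gene Mycn, Akap5, Igsf1, Nrep, the proliferation marker Mki67 and Dbh, an enzyme of noradrenaline synthesis, changed by -2.83, -2.69, -2.53, -2.34, -2.31, -2.28 and -2.26.

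**Figure D1:**
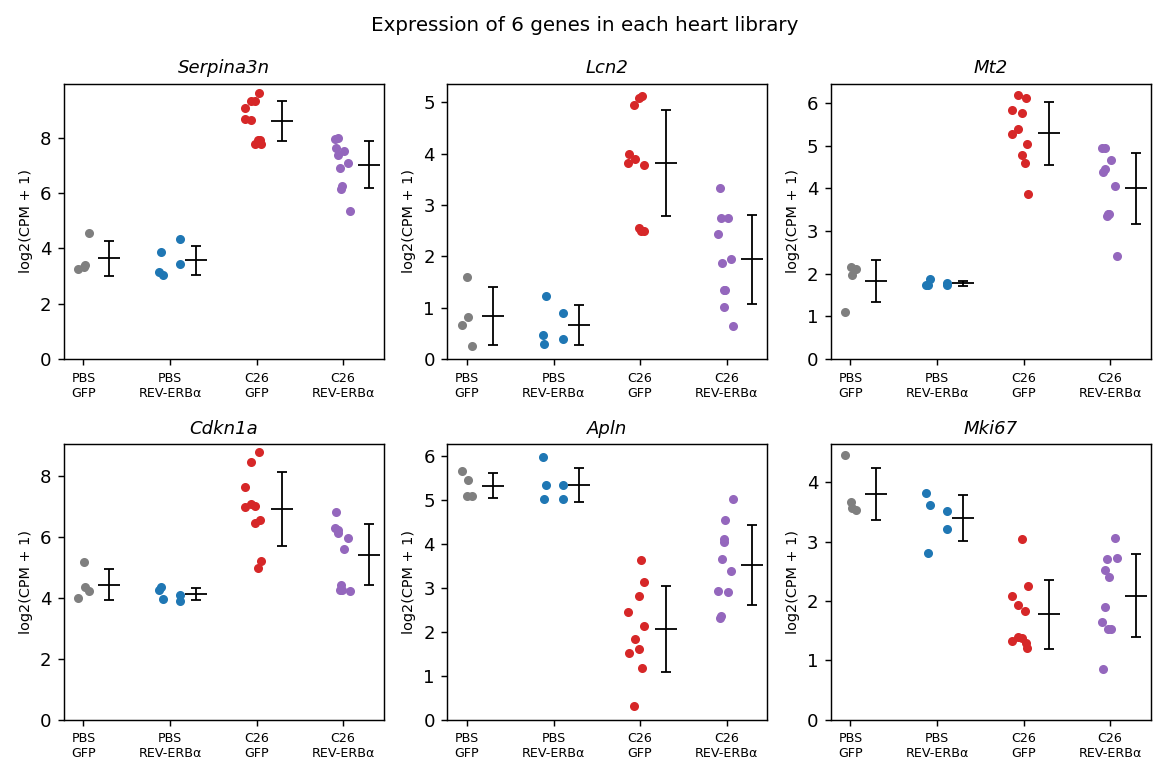
Expression as log2(CPM + 1) of Serpina3n, Lcn2, Mt2, Cdkn1a, Apln and Mki67 in each heart library of the 4 groups, with points for libraries and bars for the mean and SD of the plotted values. The C26_GFP hearts lie at 216 to 789 CPM for Serpina3n and the PBS_GFP hearts at 8.61 to 22.8 CPM, and for Apln the C26_GFP hearts lie at 0.25 to 11.4 CPM and the PBS_GFP hearts at 32.9 to 49.6 CPM.

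Across all tested genes, 3642 changed in C26_GFP hearts, 1836 higher and 1806 lower, with 269 rising and 186 falling more than 2-fold. Among 22 acute phase genes and targets of interleukin-6 and STAT3, 16 rose, none fell and 6 did not pass (19 rose when adjusted over the list alone). The list's median change was 1.39, and it rose as a group (camera adjusted p = 6.44e-13, adjusted p = 0.0638 with an estimated correlation). Within it, the cytokine receptor gene Osmr rose by 1.69 ± 0.15, its signalling partner Stat3 by 0.68 ± 0.07 and the feedback inhibitor Socs3 by 2.10 ± 0.24 (edgeR adjusted p = 2.2e-08, 5.34e-08 and 5.06e-07). Of 21 glucocorticoid receptor targets, 12 rose and 9 did not pass (13 rose adjusted over the list alone), among them Mt1 by 2.44 ± 0.34, Fkbp5 by 2.17 ± 0.43 and Plin4 by 1.02 ± 0.18. This list, which shares Lcn2 with the acute phase list, rose as a group (camera adjusted p = 9.59e-07, adjusted p = 0.375 with an estimated correlation). Of 16 macrophage and monocyte markers, 8 rose (11 adjusted over the list alone), including the complement genes C1qa by 0.49 ± 0.11 and C1qb by 0.68 ± 0.10. Camera gave the macrophage list an adjusted p of 0.00018 (adjusted p = 0.375 with an estimated correlation). Of 20 NF-kB and chemokine genes, 9 rose and 1 fell (the same counts adjusted over the list alone), with the adhesion molecule gene Icam1 higher by 0.94 ± 0.13 and Selp by 2.14 ± 0.56. Camera gave the NF-kB list an adjusted p of 0.0428 (adjusted p = 0.448 with an estimated correlation). It did not pass without PBS_GFP replicate 1 or 2 or C26_GFP replicate 3, 6, 8 or 9 (camera adjusted p from 0.0514 to 0.079).

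Lists of calcium handling, oxidative phosphorylation, TCA cycle and sarcomere genes fell. Of 25 calcium handling and ion channel genes, 14 fell and 11 did not pass (14 fell and 1 rose adjusted over the list alone). The calcium-binding protein gene Casq2 stood at -0.90 ± 0.13, the kinase gene Camk2d at -0.76 ± 0.11, the pacemaker channel gene Hcn2 at -1.05 ± 0.20 and the calcium release channel gene Ryr2 at -0.34 ± 0.08. Camera gave the calcium handling list an adjusted p of 3.73e-05 (adjusted p = 0.375 with an estimated correlation). Of 54 nuclear genes of oxidative phosphorylation, 26 fell (28 fell and 1 rose adjusted over the list alone), with a median of -0.20 and with Cycs, which encodes cytochrome c, at -0.66 ± 0.10. Camera gave the oxidative phosphorylation list an adjusted p of 2.17e-07 (adjusted p = 0.499 with an estimated correlation). Of 23 genes of the TCA cycle, 11 fell and 1 rose (the same counts adjusted over the list alone), for example Idh3a at -0.46 ± 0.07 and Dlst at -0.53 ± 0.08. Camera gave the TCA cycle list an adjusted p of 0.000448 (adjusted p = 0.448 with an estimated correlation). Of 19 sarcomere genes, 10 fell and 3 rose (the same counts adjusted over the list alone), with Tpm1 at -0.85 ± 0.11, Actc1 at -0.92 ± 0.16 and Myom2 at 1.09 ± 0.20. Camera gave the sarcomere list an adjusted p of 0.00435 (adjusted p = 0.439 with an estimated correlation). The 12 cardiomyocyte markers, which share members with those lists, also moved down, 7 of them falling and 1 rising, here and adjusted over the list alone. Camera gave the cardiomyocyte markers an adjusted p of 0.00435 (adjusted p = 0.375 with an estimated correlation). Among 17 cell cycle genes, 7 fell, here and adjusted over the list alone, with Top2a at -2.19 ± 0.42. Camera gave the cell cycle list an adjusted p of 0.000164 (adjusted p = 0.0638 with an estimated correlation).

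Lipid, protein turnover and clock genes changed as well. Of 38 genes of fatty acid oxidation and PPAR targets, 16 rose and 1 fell (18 and 1 adjusted over the list alone). The lipase genes Lipe and Pnpla2 rose by 1.16 ± 0.18 and 1.02 ± 0.19. Camera gave the fatty acid list an adjusted p of 0.000336 (adjusted p = 0.564 with an estimated correlation). The adipocyte score was 1.31 ± 1.85 (SD, n = 4) in PBS_GFP and 2.32 ± 1.25 (SD, n = 10) in C26_GFP hearts. Of 8 adipocyte markers 1 rose, here and adjusted over the list alone, which was Lipe, and that list did not pass (camera adjusted p = 0.128). Of 20 ubiquitin ligase and FOXO atrophy genes, 10 rose and 2 fell (11 and 2 adjusted over the list alone), with the muscle ligase genes Trim63 higher by 0.54 ± 0.15 and Fbxo32 by 0.37 ± 0.13. Camera gave the atrophy list an adjusted p of 0.0313 (adjusted p = 0.473 with an estimated correlation). Without PBS_GFP replicate 2 it did not pass (camera adjusted p = 0.0516). Autophagy and lysosome genes rose in 9 of 28 cases and fell in 1 (11 and 2 adjusted over the list alone), with Bnip3 at 1.36 ± 0.29 and Ctsl at 0.95 ± 0.20. Camera gave the autophagy list an adjusted p of 0.00282 (adjusted p = 0.448 with an estimated correlation). In the arm of the clock that REV-ERB represses, 4 of 6 genes rose (5 adjusted over the list alone), Arntl (Bmal1) by 1.83 ± 0.57 and Npas2 by 1.75 ± 0.35 among them. Camera gave the REV-ERB-repressed arm an adjusted p of 0.00435 (adjusted p = 0.412 with an estimated correlation). In the PER/CRY and D-box output arm, 5 of 12 genes fell (6 fell and 1 rose adjusted over the list alone), with Dbp at -1.11 ± 0.30 and Hlf at -0.69 ± 0.15. Camera gave the D-box arm an adjusted p of 0.0318 (adjusted p = 0.552 with an estimated correlation). Without C26_GFP replicate 6 it did not pass (camera adjusted p = 0.0852). Clock genes vary over the day, and the time of tissue collection is not given in the sources used here. Cytosolic ribosomal protein genes rose in 18 of 43 cases (18 rose and 1 fell adjusted over the list alone), with a median of 0.24. Camera gave the ribosomal protein list an adjusted p of 2.68e-06 (adjusted p = 0.48 with an estimated correlation). Of 29 insulin, IGF and mTOR genes, 10 rose and 2 fell (11 and 2 adjusted over the list alone), with Igfbp4 at 1.42 ± 0.24 (camera adjusted p = 0.0235, adjusted p = 0.375 with an estimated correlation). Both skeletal muscle markers tested, Myl1 and Ckm, fell, here and adjusted over the list alone (camera adjusted p = 0.0312, adjusted p = 0.375 with an estimated correlation). Their list did not pass without PBS_GFP replicate 1 (camera adjusted p = 0.0516). The mean level of these 2 genes was 8.83 log2 CPM in PBS_GFP and 8.15 in C26_GFP hearts. At such levels in heart samples, their transcripts need not come from skeletal muscle.

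The other lists did not pass in C26_GFP hearts. The 15 cardiac fetal and stress genes moved both ways, 3 up and 3 down, with the slow myosin gene Myh7 at 1.15 ± 0.22 and the skeletal actin gene Acta1 at -2.02 ± 0.29, a list median of 0.05 and a mean of -0.01. For the ER chaperone, proteasome, hepatocyte, platelet and Schwann cell lists the sign of the median, the mean and the test also differed. The hepatocyte markers Alb and Apob passed as lower, at -2.52 ± 0.90 and -2.56 ± 0.95 (edgeR adjusted p = 0.035 and 0.0427), and without PBS_GFP replicate 2 the values were 1.48 and 4.08 (edgeR adjusted p = 0.524 and 0.209). That heart had a hepatocyte marker score of 3.65 against -0.501 to -0.417 in the other PBS_GFP hearts. The count of changed genes was 1972 without the 5 libraries above 10000000 counts and 2294 when every library was thinned to the smallest total, and no list passed with an estimated correlation. Of the 18 lists that passed, 15 also passed without the 5 libraries above 10000000 counts. With thinned libraries 17 of them passed, and without the 9 libraries with high atrial markers 17 did.

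**Figure D2:**
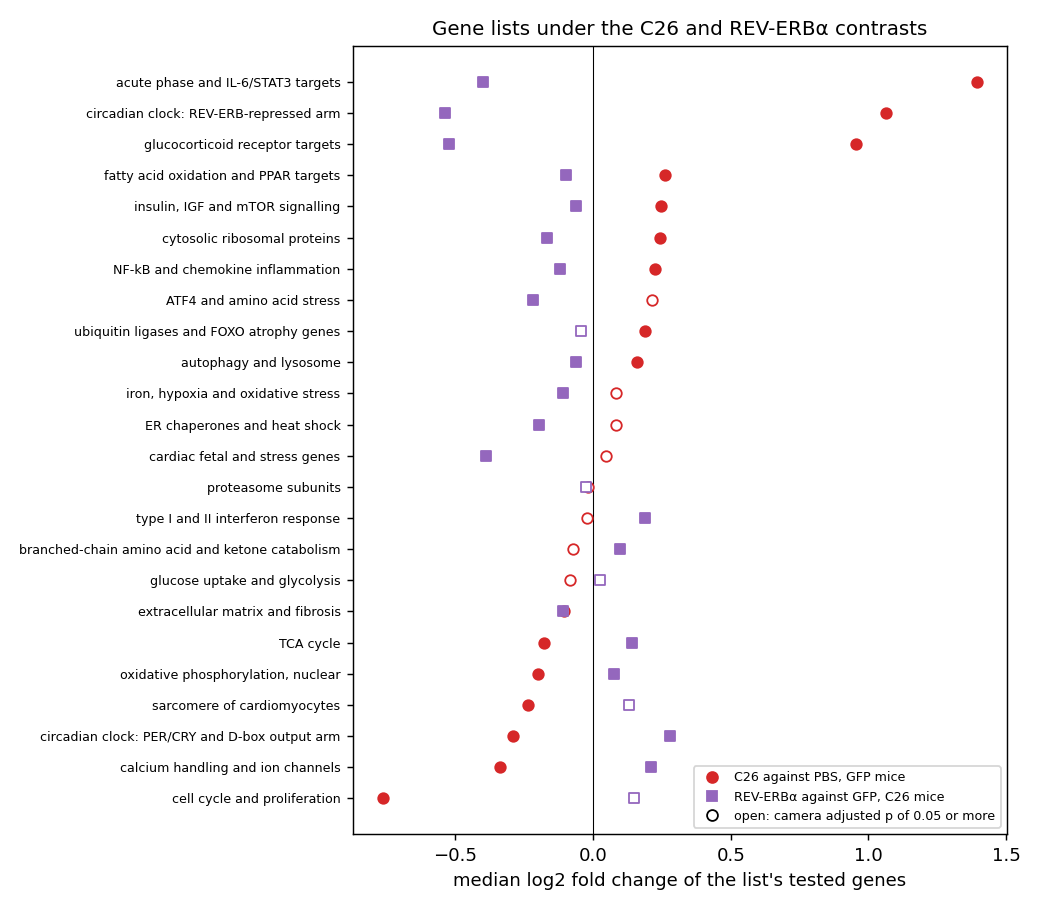
Median log2 fold change over the tested members of each pathway list, with circles for C26 against PBS in GFP mice and squares for REV-ERBα against GFP in C26 mice, filled where the camera adjusted p was under 0.05. The acute phase list stands at 1.39 for the tumour in GFP mice and at -0.40 for REV-ERBα in tumour-bearing mice, and the calcium handling list at -0.34 and 0.21.

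The second comparison asked how the hepatocyte REV-ERBα vector alters the heart of tumour-bearing mice. Lcn2 fell from 16.5 ± 11.5 CPM (SD, n = 10) in C26_GFP to 3.51 ± 2.70 CPM (SD, n = 10) in C26_REVERBa hearts, a log2 change of -2.22 ± 0.41 (edgeR adjusted p = 0.00655). Serpina3n fell from 433 ± 209 to 149 ± 73.4 CPM (SD, n = 10 each), a change of -1.54 ± 0.29 (edgeR adjusted p = 0.00655), and Cdkn1a from 163 ± 136 to 51.9 ± 32.7 CPM, a change of -1.66 ± 0.40 (edgeR adjusted p = 0.016). Apln rose from 4.11 ± 3.43 to 12.7 ± 8.76 CPM, a change of 1.62 ± 0.38 (edgeR adjusted p = 0.0147), and its receptor gene Aplnr rose by 1.23 ± 0.28 (edgeR adjusted p = 0.0143). For Lcn2, Serpina3n, Cdkn1a and Apln the C26_REVERBa mean lay between those of C26_GFP and of both PBS groups. The immediate early genes Fos, Nr4a1 and Atf3 changed by -1.81, -1.60 and -1.48, Scd3 by -1.59 and Mt2 by -1.30. Igsf1, Akap5, Rtn4r, Nrep, the smooth muscle actin gene Acta2 and Mrgprh rose by 1.38, 1.27, 1.22, 1.17, 1.13 and 1.06.

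In all, 931 genes changed between the tumour-bearing groups, 485 higher and 446 lower in C26_REVERBa hearts, with 20 rising and 34 falling more than 2-fold. With upper quartile scaling 561 were higher and 351 lower, and without a filter on low counts 298 were higher and 411 lower. Acute phase and STAT3 target genes fell in 9 of 22 cases (17 adjusted over the list alone), with a median of -0.40, Lrg1 at -1.15 ± 0.20 and Timp1 at -1.34 ± 0.33. Camera gave the acute phase list an adjusted p of 5.34e-08 (adjusted p = 0.268 with an estimated correlation). Glucocorticoid receptor targets fell in 9 of 21 cases (13 adjusted over the list alone), with Mt1 at -1.05 ± 0.21 and Fkbp5 at -1.06 ± 0.28. Camera gave the glucocorticoid list an adjusted p of 5.34e-08 (adjusted p = 0.268 with an estimated correlation). The amino acid stress genes of the ATF4 pathway fell in 6 of 20 cases (7 adjusted over the list alone), with the transcription factor gene Atf4 at -0.32 ± 0.09. Camera gave the ATF4 list an adjusted p of 0.000634 (adjusted p = 0.268 with an estimated correlation). Of 15 cardiac fetal and stress genes, 4 fell and 1 rose (9 and 1 adjusted over the list alone), with Myh7 at -0.80 ± 0.16. Camera gave the cardiac stress list an adjusted p of 0.00214 (adjusted p = 0.268 with an estimated correlation). Of 43 ribosomal protein genes, 4 fell (20 adjusted over the list alone), with a median of -0.17. Camera gave the ribosomal protein list an adjusted p of 2.01e-10 (adjusted p = 0.268 with an estimated correlation). Macrophage markers fell in 3 of 16 cases (5 adjusted over the list alone), namely Lyve1, C1qa and C1qb at -0.55, -0.29 and -0.27. Camera gave the macrophage list an adjusted p of 0.00665 (adjusted p = 0.401 with an estimated correlation). With depth class as a covariate it did not pass (camera adjusted p = 0.0583). The libraries above 10000000 counts were 2 of PBS_GFP and 3 of C26_GFP. In the arm of the clock repressed by REV-ERB, 2 of 6 genes fell (6 adjusted over the list alone), with Nfil3 at -0.79 ± 0.20. Camera gave the REV-ERB-repressed arm an adjusted p of 0.000484 (adjusted p = 0.268 with an estimated correlation).

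Calcium handling and ion channel genes rose in 8 of 25 cases (15 adjusted over the list alone), with Camk2d at 0.37 ± 0.08, Casq2 at 0.39 ± 0.10 and the potassium channel gene Kcnj2 at 0.45 ± 0.11. Camera gave the calcium handling list an adjusted p of 6.91e-06 (adjusted p = 0.268 with an estimated correlation). Of 23 TCA cycle genes, 7 rose and 1 fell (11 and 1 adjusted over the list alone), with Dld at 0.28 ± 0.05 and Cs, which encodes citrate synthase, at 0.21 ± 0.05. Camera gave the TCA cycle list an adjusted p of 1.39e-05 (adjusted p = 0.268 with an estimated correlation). Oxidative phosphorylation genes rose in 6 of 54 cases (7 adjusted over the list alone), with Cycs at 0.34 ± 0.08. Camera gave the oxidative phosphorylation list an adjusted p of 6.3e-05 (adjusted p = 0.576 with an estimated correlation). Branched-chain amino acid and ketone catabolism genes rose in 5 of 20 cases (7 rose and 1 fell adjusted over the list alone), including the ketone body enzyme gene Oxct1 by 0.49 ± 0.12. Camera gave the branched-chain list an adjusted p of 0.00712 (adjusted p = 0.401 with an estimated correlation). In the D-box output arm of the clock 4 of 12 genes rose (6 adjusted over the list alone), with Dbp at 0.86 ± 0.24 and Per3 at 0.41 ± 0.11. Camera gave the D-box arm an adjusted p of 0.000343 (adjusted p = 0.268 with an estimated correlation). The unknown time of tissue collection bears on both clock arms here too. The adult myosin gene Myh6 rose by 0.28 ± 0.09 and was the 1 of 12 cardiomyocyte markers to pass (4 adjusted over the list alone; camera adjusted p = 0.0059, adjusted p = 0.268 with an estimated correlation). None of 29 interferon response genes passed, here or adjusted over the list alone, although the list lay above the other genes with a median of 0.19. Camera gave the interferon list an adjusted p of 0.000229 (adjusted p = 0.401 with an estimated correlation).

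A further 7 lists passed as lower. ER chaperones fell in 2 of 28 cases (camera adjusted p = 0.000229, adjusted p = 0.401 with an estimated correlation). Fatty acid genes fell in 2 of 38, Pnpla2 and Acot1 at -0.47 and -0.92 (camera adjusted p = 0.00712, adjusted p = 0.625 with an estimated correlation). Autophagy genes fell in 3 of 28 cases and rose in 1 (camera adjusted p = 0.0187, adjusted p = 0.471 with an estimated correlation). NF-kB genes fell in 3 of 20, with Icam1 at -0.40 ± 0.09 (camera adjusted p = 0.0435, adjusted p = 0.401 with an estimated correlation). Matrix genes fell in 5 of 35 cases, including Lox, a collagen crosslinking enzyme gene, at -1.13 ± 0.27. Camera gave the matrix list an adjusted p of 0.0435 (adjusted p = 0.625 with an estimated correlation). Iron and oxidative stress genes fell in 4 of 27 cases and rose in 2 (camera adjusted p = 0.0435, adjusted p = 0.268 with an estimated correlation). Insulin and mTOR genes fell in 2 of 29 and rose in 1, with Irs2 at -0.97 ± 0.25 (camera adjusted p = 0.0471, adjusted p = 0.268 with an estimated correlation). Adjusted over each list alone, the falls were 5, 4, 7, 3, 5, 7 and 7 and the rises 0, 0, 1, 0, 0, 5 and 1. The fatty acid, NF-kB, matrix, iron and insulin lists lost the call (camera adjusted p from 0.05 to 0.224) without any 1 of 2, 9, 11, 9 and 11 libraries. These were C26_GFP replicate 1 and C26_REVERBa replicate 9 for fatty acid genes, and for the others C26_GFP replicates 1, 2, 3, 5, 6, 7, 8, 9 and 10, C26_REVERBa replicates 1, 2, 3, 4, 6, 7, 8 and 9 and PBS_REVERBa replicate 3. The muscle ligase genes Trim63 and Fbxo32 did not pass, at -0.29 ± 0.11 and 0.10 ± 0.10 (edgeR adjusted p = 0.0996 and 0.562). The hepatocyte marker Alb had 1.26 ± 1.5 CPM in C26_GFP and 7.22 ± 11.7 CPM (SD, n = 10 each) in C26_REVERBa hearts. The difference of 2.37 ± 0.77 did not pass (edgeR adjusted p = 0.0542). None of 11 hepatocyte markers passed (1 rose adjusted over the list alone), nor did the list (camera adjusted p = 0.0796, adjusted p = 0.66 with an estimated correlation). The list had a camera adjusted p of 0.0165 to 0.0422 without PBS_GFP replicate 1, 2, 3 or 4, C26_GFP replicate 5 or C26_REVERBa replicate 1, 6, 7 or 8, and of 0.00125 without the 5 libraries above 10000000 counts. The adipocyte list had a median of 2.23, with none of 8 members passing (6 rose adjusted over the list alone) and a test in the other direction (camera adjusted p = 0.701). The adipocyte score was 2.32 ± 1.25 (SD, n = 10) in C26_GFP and 2.36 ± 2.04 (SD, n = 10) in C26_REVERBa hearts, with 7.06 in C26_REVERBa replicate 9. The adipocyte, atrial, mesothelium and platelet lists had tests that differed in sign from their medians or means.

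The number of genes changed by REV-ERBα in tumour-bearing mice depended on single libraries. It was 295, 434, 444, 513, 572 and 1778 without C26_REVERBa replicates 7, 1, 10, 4, 3 and 9, and 335, 397, 573, 590 and 1723 without C26_GFP replicates 10, 7, 1, 2 and 6, against 931 with all libraries. It was 413 with all libraries thinned to the smallest total, 327 with only these groups in the fit and 1772 with limma voom and sample weights, and no list passed with an estimated correlation. Of the 21 lists that passed, 18 also passed with depth class as a covariate and 20 without the libraries above 10000000 counts. With thinned libraries 19 of them passed, and without the libraries with high atrial markers 19 did. By fry 14 lists passed, 12 of them among the 21. The branched-chain, macrophage and autophagy lists were among those that did not pass (fry adjusted p = 0.07, 0.0829 and 0.12).

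The third comparison asked what the REV-ERBα vector does to the heart without a tumour, in 5 PBS_REVERBa against 4 PBS_GFP hearts. Serpina3n had 11.5 ± 4.90 CPM (SD, n = 5) against 12.5 ± 6.89 CPM (SD, n = 4), Apln 40.6 ± 12.6 against 39.5 ± 8.10 CPM, and Cdkn1a 16.5 ± 2.38 against 21.9 ± 9.23 CPM. No gene changed by edgeR's quasi-likelihood test, and the counts were 1 by DESeq2 and 1 by limma voom. An unadjusted edgeR p under 0.05 was found for 530 of 12928 genes, where chance gives about 646. The fit shared 1 estimate of the spread with the tumour-bearing groups. The smallest p-values belonged to the heat shock gene Hspa1b at -1.45 ± 0.34, Alkbh3 at -0.39 ± 0.09, Dlg5 at 0.32 ± 0.08, Has3 at 0.82 ± 0.21 and Aftph at -0.28 ± 0.07, none of which passed (edgeR adjusted p = 1 each). The hepatocyte, oxidative phosphorylation, iron, macrophage and platelet lists lay below the other genes, with medians of -4.23, -0.05, -0.10, -0.14 and -1.04. Their camera adjusted p-values were 0.0167, 0.0167, 0.0242, 0.0494 and 0.0494 (adjusted p = 0.987, 0.987, 0.939, 0.987 and 0.987 with an estimated correlation). No member of these 5 lists passed, and adjusted over the list alone 4 hepatocyte markers were lower and no member of the other 4 lists passed. The hepatocyte score was 3.65 in PBS_GFP replicate 2, -0.501 to -0.417 in the other PBS_GFP hearts and -0.803 to -0.242 in PBS_REVERBa hearts. Without that library the hepatocyte list had a camera adjusted p of 0.989, and without PBS_REVERBa replicate 5 one of 0.0738. The number of lists was 0 without the 5 libraries above 10000000 counts. It was 1, 2, 10 and 0 without PBS_GFP replicate 1, PBS_REVERBa replicate 2, PBS_GFP replicate 4 and PBS_REVERBa replicate 5, and 3 without each of 15 C26 libraries. Without C26_REVERBa replicate 9 the gene Hspa1b passed, and in simulated counts for this comparison the test recovered 51% of 100 genes changed 1.5-fold and 69% of 100 changed 2-fold. Those simulated counts had the same spread in all groups.

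The fourth comparison asked what the tumour does to the heart of mice that received REV-ERBα. Serpina3n rose by 3.73 ± 0.48 (edgeR adjusted p = 1.57e-05), from 11.5 ± 4.90 CPM (SD, n = 5) to 149 ± 73.4 CPM (SD, n = 10). Mt2 rose by 2.81 ± 0.55 (edgeR adjusted p = 0.00183) and the cytokine receptor gene Csf2rb2 by 2.51 ± 0.36 (edgeR adjusted p = 5e-05). Mycn fell from 19.5 to 3.94 CPM, a change of -2.28 ± 0.27 (edgeR adjusted p = 3.04e-06), and Apln changed by -1.67 ± 0.38 (edgeR adjusted p = 0.00751). In all, 935 genes changed, 523 higher and 412 lower (542 and 595 with limma voom and sample weights). Acute phase genes rose in 11 of 22 cases (17 adjusted over the list alone; camera adjusted p = 7.18e-15, adjusted p = 0.0418 with an estimated correlation). Cell cycle genes fell in 3 of 17 (5 adjusted over the list alone; camera adjusted p = 7.2e-05, adjusted p = 0.0478 with an estimated correlation). Macrophage markers rose in 7 of 16 cases (10 adjusted over the list alone; camera adjusted p = 7.26e-07, adjusted p = 0.28 with an estimated correlation). Fatty acid genes rose in 8 of 38 (14 adjusted over the list alone; camera adjusted p = 1.22e-06, adjusted p = 0.549 with an estimated correlation). The adipocyte markers had a median of 1.94, with 1 of 8 rising, here and adjusted over the list alone (Lipe, which is in both lists), and the list did not pass (camera adjusted p = 0.459). The adipocyte score was 7.06 in C26_REVERBa replicate 9 and at most 3.60 in the other C26_REVERBa hearts. Glucocorticoid targets rose in 5 of 21 cases (11 adjusted over the list alone; camera adjusted p = 1.41e-05, adjusted p = 0.549 with an estimated correlation). Matrix genes fell in 7 of 35 and rose in 2 (15 and 3 adjusted over the list alone; camera adjusted p = 4.26e-05, adjusted p = 0.549 with an estimated correlation). Interferon response genes rose in 3 of 29 cases (5 adjusted over the list alone; camera adjusted p = 0.000866, adjusted p = 0.551 with an estimated correlation). Sarcomere genes fell in 3 of 19 (7 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.019, adjusted p = 0.549 with an estimated correlation). The sarcomere list did not pass without PBS_REVERBa replicate 4 (camera adjusted p = 0.19) or with the hepatocyte marker score as a covariate (camera adjusted p = 0.0542). The hepatocyte list rose with 1 of 11 members passing (9 adjusted over the list alone; camera adjusted p = 7.2e-05, adjusted p = 0.549 with an estimated correlation). Alb reached 38.5 CPM in C26_REVERBa replicate 10.

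The other 9 lists that passed in this comparison held 0 to 5 changed genes each. Autophagy genes rose in 5 of 28 cases (7 adjusted over the list alone), with Bnip3 at 0.91 ± 0.26 (camera adjusted p = 0.0135, adjusted p = 0.551 with an estimated correlation). ER chaperones fell in 4 of 28 and rose in 1, here and adjusted over the list alone (camera adjusted p = 0.0184, adjusted p = 0.596 with an estimated correlation). Calcium handling genes fell in 3 of 25, here and adjusted over the list alone, with Casq2 at -0.47 ± 0.12 and Camk2d at -0.42 ± 0.10 (camera adjusted p = 0.0342, adjusted p = 0.574 with an estimated correlation). Cardiac stress genes fell in 2 of 15 (4 adjusted over the list alone), with Acta1 at -1.29 ± 0.28 (camera adjusted p = 0.0421, adjusted p = 0.551 with an estimated correlation). No gene of 54 in oxidative phosphorylation passed, here or adjusted over the list alone, and the list lay below the other genes with a median of -0.06 (camera adjusted p = 0.019, adjusted p = 0.752 with an estimated correlation). Among markers of other cell types, 1 of 11 for smooth muscle fell (3 adjusted over the list alone; camera adjusted p = 0.0184, adjusted p = 0.549 with an estimated correlation). No mesothelial, erythroid or platelet marker passed among 7, 3 and 8, and 6, 2 and 0 rose adjusted over the list alone, with list means of 2.27, 1.10 and 1.05. These lists lay above the other genes, with camera adjusted p-values of 0.0235, 0.0377 and 0.0421 (adjusted p = 0.551, 0.549 and 0.551 with an estimated correlation). The autophagy, calcium handling, cardiac stress, oxidative phosphorylation, mesothelial, erythroid and platelet lists lost the call (camera adjusted p from 0.0511 to 0.368) when 1 library was left out, the libraries being PBS_REVERBa replicates 1, 2, 3 and 4, C26_GFP replicate 6 and C26_REVERBa replicates 1, 2, 3, 4, 7, 8, 9 and 10. Without the 9 libraries with high atrial markers the autophagy, calcium handling, smooth muscle, mesothelial, erythroid and platelet lists did not pass (camera adjusted p from 0.0631 to 0.246). With the hepatocyte marker score as a covariate the calcium handling, cardiac stress, smooth muscle, mesothelial, erythroid and platelet lists did not pass (camera adjusted p from 0.0542 to 0.592). The count of genes was 521 and 476 without PBS_REVERBa replicates 2 and 5, 416 without the 9 libraries with high atrial markers, 367 with the hepatocyte marker score as a covariate and 497 with thinned libraries.

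The tumour effects in the 2 vector backgrounds share no library and could be set side by side. Of 1836 genes higher with a tumour in GFP mice and 523 in REV-ERBα mice, 424 were in both, where 74.3 would be in both if the lists were independent. Of 1806 and 412 lower genes, 320 were in both, against 57.6, and no gene passed in opposite directions. Of the 3642 genes changed in GFP mice, 3394 (93.2%) had the same sign in REV-ERBα mice, with a median absolute log2 change of 0.42 in GFP mice and 0.20 in REV-ERBα mice. These genes were chosen by their change in GFP mice, which favours larger values there.

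**Figure D3:**
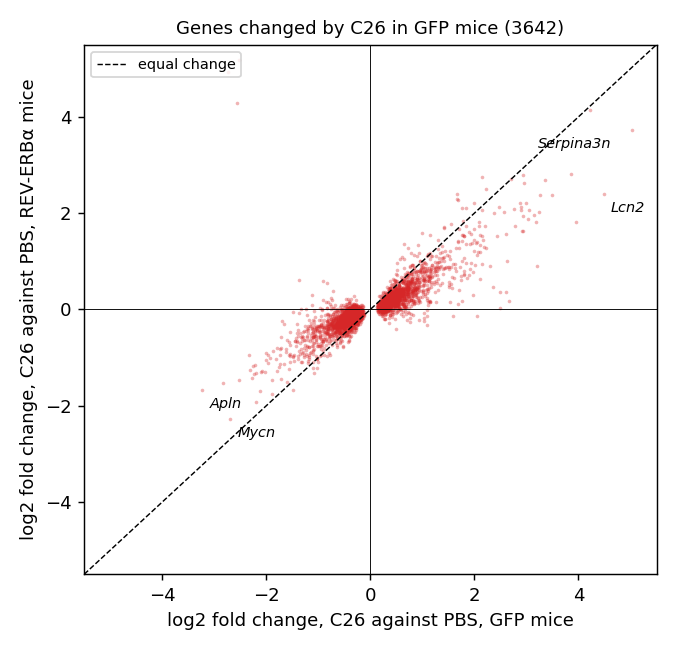
Log2 fold change of C26 against PBS hearts in REV-ERBα mice (vertical axis) and in GFP mice (horizontal axis), 1 point for each of the 3642 genes changed in GFP mice, with a dashed line of equal change. Serpina3n lies at 5.02 and 3.73 and Apln at -3.23 and -1.67.

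The difference between the 2 tumour effects was tested as an interaction. No gene passed by edgeR's quasi-likelihood test, with a smallest adjusted p of 0.278, 1357 genes at an unadjusted p under 0.05 (chance gives about 646), and counts of 15 by DESeq2 and 4 by limma voom. The smallest p-values belonged to Dlg5, Faap20, Cd63, Emilin1 and Cirh1a, at -0.46 ± 0.10, -0.91 ± 0.20, -0.67 ± 0.14, -0.54 ± 0.12 and -0.64 ± 0.15. Serpina3n, Lcn2 and Apln were changed by REV-ERBα in tumour-bearing hearts, yet no gene was shown to differ between the tumour effects by this test. As groups, 12 lists passed with camera and none did with an estimated correlation (smallest adjusted p = 0.578). Oxidative phosphorylation, TCA cycle and calcium handling genes had positive medians of 0.14, 0.17 and 0.24, and ribosomal protein and glucocorticoid genes negative ones of -0.17 and -0.48. The acute phase list had a median of -0.30 and a mean of 0.08, with a test in the direction of the median.

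A planned comparison asked whether REV-ERBα moved the genes that the tumour changed in the opposite direction. The C26_GFP hearts were divided at random into groups of 5 in 20 draws. One group of 5 gave the tumour effect and the other the REV-ERBα effect, so that no library served both. Across the genes called in each draw, the slope of the REV-ERBα effect on the tumour effect had a median of -0.32 with a range of -0.48 to -0.15, and 89.1% of genes (80.7 to 92.9%) had opposite signs. In simulated counts with a tumour effect and no REV-ERBα effect the slope had a median of -0.005 with a range of -0.014 to 0.044, and 50.1% of genes had opposite signs. Without the division the slope was -0.38 with 95.1% opposite signs, against -0.056 and 61.5% in the simulated counts, and the covariance was -0.207 against -0.038. Genes are not independent replicates. The draws divide the same C26_GFP hearts again, so their range does not measure the spread between animals. The simulated counts hold no variation that genes share between animals, so the simulated range is narrower than that of real animals.

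A score per library gave a test with animals as replicates, and it was chosen after the data were seen. It was the mean log2 CPM of 2249 genes higher minus that of 2103 genes lower in all C26 than in all PBS hearts, without regard to the vector, set to 0 in the PBS hearts. It was 1.01 ± 0.21 (SD, n = 10) in C26_GFP and 0.67 ± 0.25 (SD, n = 10) in C26_REVERBa hearts, a difference of -0.34 (two-sided permutation test with 100000 resamples, p = 0.00465). The PBS groups, at 0.005 ± 0.045 (SD, n = 4) and -0.004 ± 0.055 (SD, n = 5), differed by -0.0095 (two-sided exact permutation test, p = 0.841). The difference between the vector's effects on the score with and without a tumour was -0.33 (permutation test, p = 0.00814). That test shuffled vector labels within tumour groups, so it asks whether the vector had any effect. It does not separate an interaction from the difference in C26 hearts. The score's genes were chosen by tumour in these same libraries, which limits what the small PBS difference can show.

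**Figure D4:**
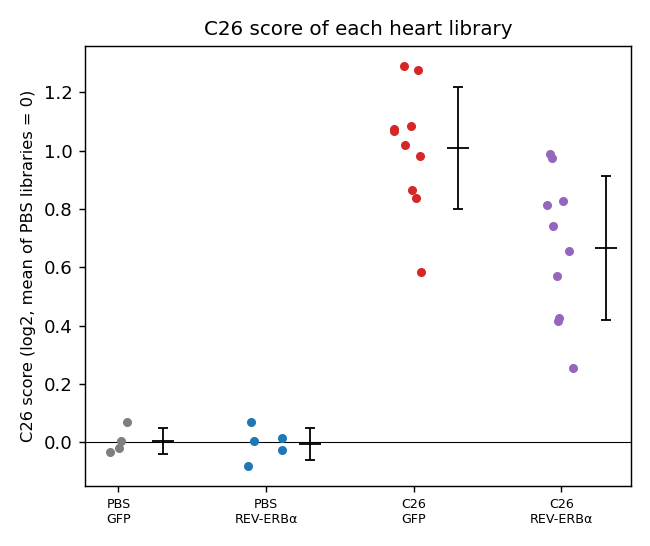
C26 score of each heart library (log2, mean of the PBS libraries set to 0) by group, with points for libraries and bars for the mean and SD. The C26_GFP hearts lie between 0.58 and 1.29, the C26_REVERBa hearts between 0.25 and 0.99, and the PBS hearts between -0.08 and 0.07.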

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

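The tests of a common liver source, of liver transcripts against vector group and of gene length were chosen only after the results were seen. The C26 score itself was also chosen then. The predictions for depth, atrial tissue, shared libraries and random splits were written before their results. For depth and atrial tissue, however, the libraries left out and the C26 score were chosen after the data were seen, so these checks were not planned.

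In C26 hearts the REV-ERBα effect had the opposite sign to the tumour effect in a median of 89.1% (80.7 to 92.9%) of the genes called for the tumour, most of which did not pass for REV-ERBα. The C26 score difference of -0.34 was -0.404 without the 5 libraries above 10000000 counts (exact permutation p = 0.00278, 7 against 10 hearts) and -0.406 without the 9 libraries with high atrial markers (exact permutation p = 0.0163, 7 against 6), which argues against depth or atrial tissue as the whole cause. The slope of -0.318 over groups of 5 that share no library was below 0 in every draw and below the lowest simulated slope of -0.014. This argues against shared C26_GFP libraries as the whole cause. The draws divide the same hearts again and are not independent, and the simulated counts hold no variation that genes share. The vector groups are the biological explanation that the design gives, while tumour mass and food intake, not analysed here, may differ between the vector groups and stay open. The slope was planned before the data were examined and the C26 score was not, and a damped tumour response stays a hypothesis.

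Transcripts of liver genes appeared in some heart libraries, with Alb at 27.8 CPM in PBS_GFP replicate 2 and 38.5 CPM in C26_REVERBa replicate 10. Across the libraries 90% of the other hepatocyte list members (9 of 10, lowest Ahsg at a Spearman rho of 0.458) followed Alb with a rho over 0.5, consistent with 1 outside source such as adhering or carried-over liver RNA. Whether it goes with the vector group of C26 mice cannot be told apart from chance, since the hepatocyte score differed by 0.797 (permutation p = 0.189) and its bootstrap interval ran from -0.287 to 1.89.

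Cytosolic ribosomal protein genes had a median of 0.242 in C26_GFP hearts. The 4299 genes outside the list within its range of counted length, 79 to 2153 bases, had a median of -0.0114. That range is too wide to match length closely. The oxidative phosphorylation genes, with a median counted length of 765 bases against 703, had a median of -0.201. That list fell with the tumour itself, so its sign is no control for length. Across all tested genes the tumour effect in GFP mice had a Spearman rho of -0.00266 with counted length, which argues against a general effect of gene length. The ribosomal protein list's median was 0.26 without the deep libraries, which argues against depth. Reads shared with pseudogenes were not tested and may contribute, and the tumour stays open as the biological explanation, since both groups received the GFP vector.

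Random splits bore on the counts. For changed genes, 1 of 100 splits, the real one, gave 3642 genes for the tumour in GFP mice (highest other 2068), 931 for REV-ERBα in C26 mice (highest other 2) and 935 for the tumour in REV-ERBα mice (highest other 188). This argues against chance for these 3 counts, within the limit of 100 splits. For the REV-ERBα effect without a tumour and for the interaction, the real count was 0, which all 100 splits reach by construction (highest others 1 and 19), so the splits decide nothing there. For lists, 3 of 100 splits, the real one among them, gave at least the 21 of REV-ERBα in C26 mice (highest other 22), a share under 0.05. It was 1 of 5 list counts tested and a random split gave more, so chance was not excluded. For the other comparisons, counting the real split, 13 splits gave at least the 18 of the tumour in GFP mice (highest other 23). For REV-ERBα without a tumour, 56 gave at least the 5 (highest other 15). For the tumour in REV-ERBα mice, 6 gave at least the 18 (highest other 24), and for the interaction 23 at least the 12 (highest other 20). These shares do not exclude chance either. Uneven splits of PBS and C26 hearts keep part of the tumour effect, so they are no pure chance reference for the tumour comparisons. The random split of C26 mice with 22 lists had 0 changed genes. Passing camera with the preset correlation is thus not strong evidence by itself.

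Single libraries stood apart from their group by Dixon's Q test in 18 of 132 groups of values tested. For independent normal values chance gives about 1 in 20, or 6.6. Single genes were tested as CPM without logs and the same libraries recur, so this chance count is only a rough guide. C26_REVERBa replicate 8 had 3376113 counts against 5439179 to 7619837 in the others, and C26_REVERBa replicate 6 a scaling factor of 0.973 against 0.997 to 1.03. The adipocyte marker score was 4.04 in PBS_GFP replicate 2 against at most 0.778, and 7.06 in C26_REVERBa replicate 9 against at most 3.60, where the T and NK cell score was 2.10 against at most 0.986. The hepatocyte score was 3.65 in PBS_GFP replicate 2, the endothelial score 6.71 in PBS_REVERBa replicate 3 and the platelet score 2.98 in C26_GFP replicate 6. Single genes stood apart as Nr1d1 at 259 CPM in PBS_REVERBa replicate 4, Serpina3n at 22.8 in PBS_GFP replicate 2, Apln at 62.0 and Mycn at 28.2 in PBS_REVERBa replicate 5, Mycn at 11.3 and Akap5 at 14.4 in C26_REVERBa replicate 7, Rtn4r at 26.8 and Igsf1 at 12.04 in C26_GFP replicate 6, Fos at 73.8 in C26_GFP replicate 8 and Csf2rb2 at 16.4 in C26_GFP replicate 9.

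For the difference of the tumour effect between vectors, 12 lists passed an interaction test by camera with the preset correlation. None passed with an estimated correlation (adjusted p of 0.578 for each) or with fry. At least as many lists came from 23 of 100 splits, the real one among them, so these calls do not exclude chance. The camera adjusted p-values were 2.54e-06 for oxidative phosphorylation, 6.85e-06 for ribosomal proteins, 5.55e-05 for the TCA cycle, 0.000228 for calcium handling, 0.000325 for interferon response, 0.00129 for the acute phase list and again 0.00129 for hepatocyte markers (0.178 without PBS_GFP replicate 2). They were 0.00419 for cardiomyocyte markers, 0.00478 for glucocorticoid targets, 0.00631 for the clock arm repressed by REV-ERB, 0.00693 for branched-chain amino acid catabolism and 0.0263 for skeletal muscle markers. The C26 score gave a permutation p of 0.00814 for the same difference. Its labels were shuffled within tumour groups, so it tests for any vector effect and does not isolate an interaction.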

How the results depend on the processing

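The tests that leave out deep or atrial libraries, that thin counts or that use a depth, atrial or hepatocyte covariate, and the C26 score, were chosen only after the results were seen. For changed genes of the tumour effect in GFP mice (3642), leaving out the libraries above 10000000 counts gave 1972 and thinning 2294, both of which use fewer libraries or counts. For REV-ERBα in C26 mice (931) the counts were 1709 at an adjusted p under 0.1, 327 with only those groups in the fit, 1772 with voom weights and 413 thinned. Leaving out the libraries above 10000000 counts gave 1317 there, and depth class as a covariate 1275. For the tumour effect in REV-ERBα mice (935) they were 1593 at an adjusted p under 0.1, 497 thinned, 416 without high atrial markers and 367 with the hepatocyte covariate. REV-ERBα without a tumour had 0 genes by edgeR, and 1 by DESeq2 (Cyp3a11), 1 with only those groups (Hspa1a) and 1 by voom (Hspa1b), genes named after their values were seen. The interaction had 0, against 15 by DESeq2 and 4 by voom (Cd63, Dld, Glrx and Leng8). The cause of these differences was not tested.

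The numbers of lists past the threshold with an estimated correlation were 2 for the tumour effect in REV-ERBα mice and 0 for each of the other 4 comparisons. For REV-ERBα in C26 mice (21 lists) fry gave 14. For REV-ERBα without a tumour (5 lists) fry gave 0, voom weights 9, no deep libraries 0, the depth covariate 3 and the hepatocyte covariate 0. The tumour effect in REV-ERBα mice (18) had 7 by fry and 11 with the hepatocyte covariate, and the interaction (12) had 0 by fry and 19 without high atrial markers. Replicate numbers did not pair the animals: the 32 pairs with 1 number had a mean correlation of -0.034 (-0.346 to 0.284), 5 were over 0.1, and 4 of 29 libraries correlated best with their own number. With the replicate block, 291 genes changed for REV-ERBα in C26 mice, 450 for the tumour in REV-ERBα mice, and 2 lists passed for REV-ERBα without a tumour.

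Leaving out each library in turn gave 2790 to 4138, 295 to 1778, 0 to 1, 476 to 1201 and 0 to 0 genes, for the tumour in GFP mice, REV-ERBα in C26 mice, REV-ERBα without a tumour, the tumour in REV-ERBα mice and the interaction, and 16 to 19, 16 to 23, 0 to 10, 12 to 20 and 10 to 16 lists. Among named genes, Alb and Apob reversed for the tumour in GFP mice, to 1.48 and 4.08, without PBS_GFP replicate 2, with -3.10 and -3.33 as the lowest values. Of the other values for 347 gene results, 11369 kept direction and side of the threshold, 556 fell below it and 189 passed; for 205 list results, 7720, 322 and 158. Removing 8 mitochondrial, ribosomal RNA and haemoglobin genes moved nothing, since 0 of them were tested. The slope of opposite effects was -0.321 at an adjusted p under 0.01, -0.318 with RLE and -0.382 without division. In the smallest library, of 3207497 counts, 1 CPM is 3.21 counts, which limits genes of low expression.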

Other observations

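No test here was chosen only after its result was seen. Cell type markers not described above moved in C26_GFP hearts as single genes. Among 13 endothelial markers 5 rose and 1 fell (6 and 1 adjusted over the list alone), with the growth factor receptor gene Flt1 at 0.54 ± 0.10 and Kdr, another receptor for the same ligand family, at -0.56 ± 0.12, and the list did not pass (camera adjusted p = 0.179). Among 13 fibroblast markers 3 rose and 2 fell, here and adjusted over the list alone, with Dcn at 0.67 ± 0.12 and Islr at -0.67 ± 0.14 (camera adjusted p = 0.43). In the matrix list 4 rose and 8 fell of 35 (4 and 9 adjusted over the list alone), with the proteases Mmp2 at 0.88 ± 0.15 and Mmp14 at 1.02 ± 0.19 against Col8a1 at -1.13 ± 0.15 and Sparc at -0.63 ± 0.10 (camera adjusted p = 0.146). The smooth muscle actin gene Acta2 was lower by -1.98 ± 0.41. Among 3 neutrophil markers 1 rose (2 adjusted over the list alone), Mmp9 at 2.49 ± 0.74 (camera adjusted p = 0.146), and the 1 tested T and NK cell marker, Cd3e, rose by 1.97 ± 0.69, here and adjusted over the list alone (camera adjusted p = 0.421). No mesothelial marker of 7 passed, here or adjusted over the list alone, with a median of 1.73 (camera adjusted p = 0.0566). The mesothelial list passed without PBS_GFP replicate 2 (camera adjusted p = 0.012) and without C26_GFP replicate 5 or 8 (0.0396 and 0.0224).

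Glucose and stress genes of C26_GFP hearts also moved in both directions. Of 27 glycolysis genes 11 fell and 5 rose (11 and 7 adjusted over the list alone), with Pkm at -0.51 ± 0.09 and the lactate transporter gene Slc16a3 at 0.93 ± 0.17 (camera adjusted p = 0.249). Of 28 chaperone genes 7 fell and 2 rose, here and adjusted over the list alone, with Hspa1b at -2.21 ± 0.28 and Hsph1 at -1.21 ± 0.17 (camera adjusted p = 0.531). Of 27 iron and oxidative stress genes 9 rose and 4 fell (10 and 4 adjusted over the list alone), with the transferrin receptor gene Tfrc at -1.62 ± 0.33 and the ferritin gene Fth1 at 0.39 ± 0.07 (camera adjusted p = 0.347). Proteasome subunits rose in 5 of 31 cases and fell in 1, here and adjusted over the list alone (camera adjusted p = 0.531).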
